A study of Mus musculus with 2 samples.

How the data were processed

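Acetylation of histone H4 at lysine 16 (H4K16ac) was profiled by CUT&Tag, in which an antibody directs a transposase to tag DNA beside the modified histone. Per the labels' protocols, the cells were mouse bone marrow-derived macrophages grown with the growth factor M-CSF at 20 ng/ml. They were treated for 2 h with R848 (100 ng/ml), a small molecule that activates the receptor TLR7. The 2 libraries came from wild-type and from KAT8-deficient cells, 1 library per group, and each has 1 peak list. KAT8 is the acetyltransferase that places most H4K16ac in mammalian cells. The genotype label of each library, WT or KAT8-cKO (read as a conditional knockout), set its group. How complete the deletion was in these cells was not measured here.

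Per the submitters' processing notes, the genome build was mm10 and the tools were Bowtie 0.12.8, MACS2 2.2.7.1 and DiffBind, with no role stated for any of them. Peak calling settings, a control library and the treatment of duplicate reads are not given in the sources used here. Each deposited list gives, per peak, a score, a fold over the peak caller's background, the −log10 of a p-value and of a q-value, and the offset of the summit. The score in the deposited lists is 10 times −log10 p without its decimals, for 99.993% of wild-type and 99.991% of KAT8-deficient peaks. The lowest −log10 p in the deposited lists was 2.01 in both, and only 46.9% of wild-type and 47.0% of KAT8-deficient peaks had a q-value under 0.05, so the lists hold many weak peaks that passed a threshold on p alone. These folds and q-values are the authors' peak caller's own and were used to rank or filter peaks within a list. Where counts of regions above 1 threshold are set side by side for both lists, they depend on the depth and background of each library and do not measure a change at a region. Read totals are not given in the sources used here, so depth was described only through the peak lists.

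Peaks of a list that touched or overlapped were to be merged into regions; none did, so regions and peaks are the same. A region counted as shared if at least 1 bp of it was covered by a region of the other list. The share expected without a relation between the lists was taken from 100 circular shifts of the other list along its chromosomes. Shares carry 95% Wilson intervals, which cover counting error over regions or genes only and say nothing about variation between animals. Ratios of a chromosome to autosomes carry 95% intervals on the log scale that take region counts as Poisson. They have the same limit and leave out variation between chromosomes. Strength within a list was ranked by −log10 q and divided into 10 groups of equal size.

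Gene positions came from a RefSeq table of GRCm38.p6, the assembly behind mm10. The table gives the start and end of each gene without strand or transcripts. The planned promoter window of 1 kb around each transcription start could therefore not be set, and a gene was counted as marked if a peak lay within 1 kb of either annotated end of the gene. A marked gene end can thus be the start or the 3′ end of a gene. A window can also overlap that of a neighbouring gene, and 14839 of 21887 protein-coding genes have windows free of any other. Likewise, the alternative of 5 kb upstream became the whole gene with 5 kb on both sides. No genome sequence was used here, and the planned comparison of base composition between shared and unshared regions was not run.

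The 21 gene lists, with 500 entries, were fixed before the data were examined; 4 entries (Ahsp, Cxcl11, Mx1 and Mx2) were not among the protein-coding genes of the table. For each list, the share of genes with a wild-type peak that lacked a KAT8-deficient peak was ranked among 10000 random lists of the same size, drawn from genes with a wild-type peak and matched within 10 groups of peak fold. The percentile describes these 2 libraries; with 1 library per group there is no test between genotypes and no p-value. Random lists treat genes as independent, which neighbouring genes with overlapping windows are not. The rule for named genes was also fixed beforehand: the 10 genes with the highest peak fold in each list among genes without a peak in the other, Kat8, up to 4 members of each gene list with the strongest peaks called in a single list (or the member with the strongest wild-type peak), and the 2 strongest unshared regions of each list. A gene that this rule takes is not reported here. Other genes named outside this rule are given as members of the fixed lists or are said to have been chosen after their values were seen. The exceptions are the single-copy Y genes, set before their values were seen, and Mthfd2l, shown only as a neighbour of Cxcl2.

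Tested on simulated data, the overlap code found the 40.1% of 58229 wild-type peaks that had been given a simulated partner and differed from a direct search at 0 of 2000 peaks. Among 200 simulated random lists, 11 fell in the outer 5%, and 196 of 200 lists of 20 genes with 11 lost were found in the upper 2.5%. The simulated genes were independent, and many fixed lists had fewer than 20 marked genes, so these rates need not hold for them. Other settings fixed before the data were examined were stricter q-value thresholds, equal numbers of peaks per list, other definitions of overlap, other windows, unmatched random lists and merging of peaks within 1 kb. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.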

Results

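To ask where H4K16ac lies in R848-treated wild-type and KAT8-deficient macrophages, the peak lists of 1 wild-type and 1 KAT8-deficient library were compared. The wild-type list held 58229 peaks covering 21.1 Mb, with a median width of 296 bp and a median fold of 2.90 over the peak caller's background. The KAT8-deficient list held 55149 peaks covering 18.96 Mb, with a median width of 285 bp and a median fold of 2.78. There was no replicate of either genotype, so every difference below is between these libraries and none could be set against variation between animals.

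Fewer H4K16ac regions at gene ends passed a strict q-value threshold in the KAT8-deficient list. At a −log10 q of at least 5, 2263 wild-type and 1093 KAT8-deficient regions lay within 1 kb of an end of a protein-coding gene, a ratio of 0.483. The ratio was 0.771 inside gene bodies, with 963 and 742 regions, and 0.916 outside genes, with 921 and 844 regions. Gene ends thus held 54.6% of the strong wild-type regions (95% interval 53.1 to 56.1) and 40.8% of the strong KAT8-deficient regions (39.0 to 42.7). Over all regions the shares at gene ends were 18.9% (18.6 to 19.2) and 18.4% (18.1 to 18.7). In total 4147 wild-type and 2679 KAT8-deficient regions reached a −log10 q of at least 5, and 1187 and 743 reached 10. The ratio of KAT8-deficient to wild-type regions at gene ends depended on the threshold: it was 0.921 over all regions, 0.861 for the strongest 20000 peaks of each list (6605 and 5690 regions) and 0.288 at a −log10 q of at least 10 (538 and 155). A count above a q-value threshold moves with the depth and background of a library and is no measure of the change in acetylation.

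The very strongest regions were common to both lists and mostly lay outside genes. At a −log10 q of at least 50, each list held 166 regions, of which 116 were outside genes, 45 in gene bodies and 5 at gene ends. The strongest in both lists was on chromosome 2 at 98666250 to 98667335 (mm10), outside genes, with a fold of 15.1 in wild type and 14.9 in the KAT8-deficient list. Others lay outside genes on chromosome 9 at 35305204 to 35305677 and on chromosome 18 at 90602124 to 90602659 in the wild-type list. Their folds in wild type and the KAT8-deficient list were 43.1 and 42.4 on chromosome 9, and 32.8 and 33.5 on chromosome 18. No filter for regions prone to artefact was applied here, and whether these regions carry H4K16ac was not tested. They are therefore not read as acetylation kept in KAT8-deficient cells.

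Of the wild-type regions, 33.2% (32.8 to 33.6) were overlapped by a KAT8-deficient region, and of the KAT8-deficient regions 35.6% (35.2 to 36.0) were overlapped by a wild-type one. Shifted lists gave 1.59% and 1.68%. Sharing rose with strength: in the strongest 10% of each list 89.3% of wild-type and 87.6% of KAT8-deficient regions were shared, against 13.8% and 15.9% in the weakest 10%. Shared regions lay at gene ends more often than unshared ones, with 34.6% (33.9 to 35.2) against 11.1% (10.8 to 11.4) in wild type and 35.0% (34.3 to 35.6) against 9.19% (8.90 to 9.50) in the KAT8-deficient list. This comparison was not made within groups of strength, so it cannot be told apart from the rise of sharing with strength. Among regions with a −log10 q of at least 5, 94.6% (93.9 to 95.3) of wild-type regions met some KAT8-deficient region, as did 96.2% (95.4 to 96.9) in the other direction. When the threshold was applied to both lists these shares were 44.2% and 68.7%. The strongest wild-type regions without a counterpart lay on chromosome 10, at 3114859 to 3115077 and at 118058288 to 118058665, both outside genes. The former had a fold of only 2.03 at a −log10 q of 21.4, the latter 7.31 at 15.5. The strongest KAT8-deficient ones lay in the bodies of Cntnap5b on chromosome 1 (100180110 to 100180357) and Litaf on chromosome 16 (10974974 to 10975296).

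**Figure D1:**
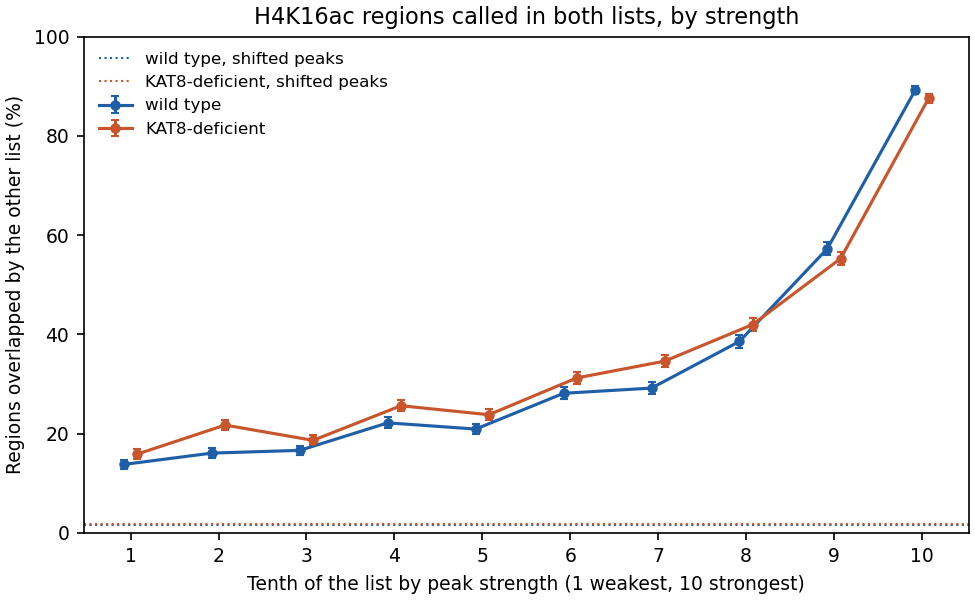
Share of H4K16ac regions overlapped by the other list (%), against the 10 groups of each list from the weakest to the strongest −log10 q, for the wild-type (blue) and KAT8-deficient (orange) library; points are shares, bars 95% Wilson intervals and dotted lines the mean of 100 shifts. Sharing rose from 13.8% to 89.3% in wild type and from 15.9% to 87.6% in the KAT8-deficient list, with shifted lists under 2%.

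With all peaks counted, most genes with an H4K16ac peak at an end in wild type also had one in the KAT8-deficient list. Of 21887 protein-coding genes, 7827 had a peak in both lists, 2422 in wild type only, 1646 in the KAT8-deficient list only and 9992 in neither. Shifted regions marked 2088 genes on average for wild type and 1976 for the KAT8-deficient list. Thus 23.6% (22.8 to 24.5) of genes with a wild-type peak lacked a KAT8-deficient one, and 17.4% (16.6 to 18.2) of genes with a KAT8-deficient peak lacked a wild-type one. This turned at a −log10 q of at least 5 in both lists, with 1719 genes in wild type only and 1004 in both. At 10 the counts were 546 and 117. The highest wild-type folds among genes without a KAT8-deficient peak belonged to Gnb1l (6.07), Vapb (5.69), a peak between Fancb and Mospd2 on the X chromosome (5.62), Ms4a4a (5.62), Phactr4 (5.49), Eif2s2 (5.43), a peak between Foxh1 and Ppp1r16a (5.39) and Dusp22 (5.29). Fancb belongs to the Fanconi anaemia DNA repair pathway, and Eif2s2 encodes the beta subunit of translation initiation factor eIF2. In the KAT8-deficient list only, the highest folds were at Pnisr (5.60), Mphosph9 (5.23), Rbm28 (5.12), Arih1 (4.91), Cfap97 (4.85), Ankrd12 (4.53), Fank1 (4.53), Rrad (4.31), Stam (4.27) and Tmcc2 (4.27).

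At several of these genes the peak was overlapped by a region of the other list that stayed outside the window. The peak at Gnb1l was overlapped by a KAT8-deficient region, and those at Pnisr, Mphosph9, Arih1, Cfap97 and Ankrd12 by wild-type regions. Of 2723 genes with a wild-type −log10 q of at least 5, 87 had no KAT8-deficient peak in the window, and at 77 of these no KAT8-deficient region overlapped the peak. Of 1311 such genes of the KAT8-deficient list, 12 had no wild-type peak in the window, and at 5 no wild-type region overlapped the peak. Kat8 itself (chromosome 7, 127912517 to 127925838) had a weak wild-type peak, with a fold of 2.46 and a −log10 q of 0.780, in a window shared with another gene, and no KAT8-deficient peak. An acetylation peak is no measure of whether the gene was deleted. Of 12 genes of the KAT8 complexes, 8 had a peak in both lists, among them Msl2, Kansl1, Kansl2 and Phf20, and Kat8 alone in wild type only (percentile 28.7).

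Of 28 TLR7 pathway genes, 20 had a peak in both lists, including Myd88, Irak4 and Traf6; 5 had one in wild type only (Irak1, Irak3, Slc15a4, Tab3 and Traf3), 0 in the KAT8-deficient list only, and 3 in neither, Tlr7 among them (percentile 34.9). In the opposite direction, 0 of 20 genes with a KAT8-deficient peak lacked a wild-type one, against a mean of 3.67 in matched lists (percentile 0.665). The 5 of 25 genes without a KAT8-deficient peak became 10 of 22 with q under 0.05 (percentile 87.1), 8 of 18 with the strongest 20000 peaks of each list (84.5) and 6 of 7 at a −log10 q of at least 5 in both lists (94.7). Of those 7 genes, only 1 lacked a KAT8-deficient peak of any strength (88.2). Over all genes, that threshold in both lists left 1719 in wild type only and 1004 in both. With windows of 3 kb 5 of 27 TLR7 pathway genes lacked a KAT8-deficient peak (56.75), and over whole genes with 5 kb on both sides 3 of 28 did (58.4). Tab3 and Irak1, which relay the signal to NF-κB, had wild-type folds of 4.89 and 3.91, and both lie on the X chromosome. Of 22 genes of NF-κB and its regulators, 13 were marked in both lists, including Rela, Relb and Rel, and 3 in wild type only (percentile 45.5): Tnfaip2, Tnfaip3, which encodes the NF-κB inhibitor A20 (fold 3.40), and Traf1 (3.45).

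Of 19 chemokine genes, 2 were marked in both lists (Cxcl1 and Cxcl10), 6 in wild type only (Ccl2, Ccl3, Ccl4, Ccl9, Cxcl2 and Cxcl16), 2 in the KAT8-deficient list only (Ccl5 and Ccl22) and 9 in neither. Thus 6 of 8 chemokine genes with a wild-type peak lacked a KAT8-deficient one, against a mean of 2.87 in matched random lists (percentile 98.9). The fold at Cxcl2, a neutrophil attractant, was 3.96 in wild type (chromosome 5, 90903492 to 90904067) and that at Cxcl16 3.27. Ccl22 and Ccl5 had KAT8-deficient folds of 3.11 and 2.75, and the Ccl5 peak did not reach a q-value under 0.05 (−log10 q 1.09). Of the 5 marked genes with windows free of other genes, 3 lacked a KAT8-deficient peak (percentile 81.8), and over whole genes with 5 kb on both sides 8 of 12 did (99.995). With the strongest 20000 peaks of each list 3 of 3 genes lacked one, too few to reach the upper 2.5%.

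**Figure D2:**
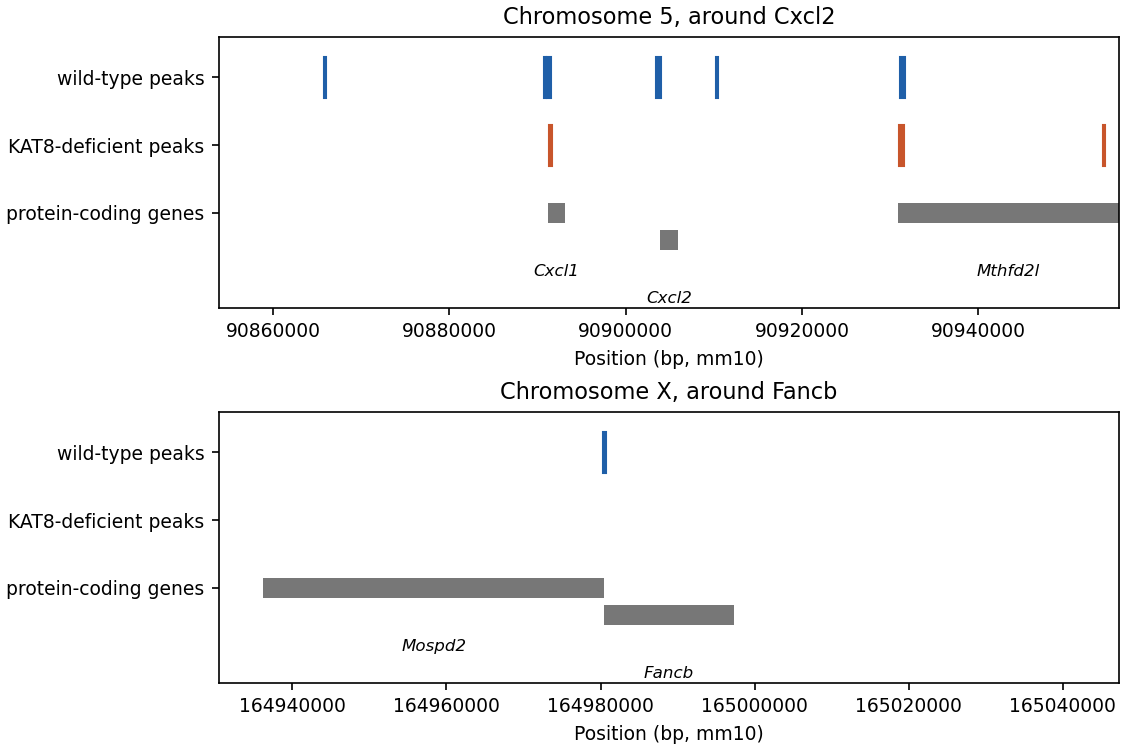
Peaks of the wild-type (blue) and KAT8-deficient (orange) list and protein-coding genes (grey) by position in bp on mm10, around Cxcl2 on chromosome 5 and around Fancb on chromosome X. The wild-type peak at the end of Cxcl2 and the one between Mospd2 and Fancb had no KAT8-deficient counterpart, while peaks at Cxcl1 and Mthfd2l were in both lists.

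Inflammatory cytokine genes were divided between the lists. Of 22, 6 were marked in both (Il12b, Il27, Ebi3, Il15, Csf1 and Tnfsf9), 4 in wild type only (Il10, Il1rn, Lif and Tnf), 3 in the KAT8-deficient list only (Il12a, Il1a and Ptgs2) and 9 in neither, Il6 and Il1b among them (percentile 66.8). Il10 and Il1rn, which encode an anti-inflammatory cytokine and the interleukin-1 receptor antagonist, had wild-type folds of 3.55 and 3.44, and Il1a and Ptgs2 each had a KAT8-deficient fold of 2.99. Of 40 interferon and interferon-stimulated genes, 24 were marked in both lists, including Stat2, Ifit1 and Irf7. Another 8 were marked in wild type only, led by Oasl2 (4.02) and Oas1a (3.31), and 3 in the KAT8-deficient list only, Rsad2 (3.31), Usp18 (2.99) and Adar (percentile 22.3, or 2.35 with q under 0.05, where 7 of 26 genes lacked a KAT8-deficient peak). Of 23 immediate early genes, the first to be transcribed after stimulation, 7 were marked in both lists, including Fos, Jun and Egr1. In wild type only there were 8, led by Klf6 (3.77) and Jund (3.30), and in the KAT8-deficient list only 3, Ier5 (3.20), Dusp1 (2.89) and Ier3 (percentile 95.4). This percentile depended on the settings: it was 28.1 with windows of 3 kb, 4.99 over whole genes with 5 kb on both sides, 97.7 matched on −log10 q and 99.3 without matching.

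Of 28 macrophage identity genes, 7 were marked in both lists, including Spi1, Cebpa and Cd14; 8 in wild type only, including Csf1r, Adgre1, Tyrobp (3.31) and Runx1 (2.73); and 2 in the KAT8-deficient list only, Mitf (3.59) and Itgam (2.89). The percentile was 80.2 against strength-matched lists and 99.2 without matching. Of 12 genes of alternative activation, 5 were marked in both lists, 2 in wild type only, Il4ra (4.40) and Irf4 (3.18), and 1 in the KAT8-deficient list only, Chil3 (2.34), at percentile 47.2. The peaks at Runx1 (−log10 q 0.955) and Chil3 (0.374) did not reach a q-value under 0.05.

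Of 41 nuclear-encoded genes of the respiratory chain, which makes the proton gradient in mitochondria, 36 were marked in both lists and 2 in wild type only, among them Ndufs4 (4.40). Thus 2 of 38 marked genes lacked a KAT8-deficient peak, against a mean of 7.58 in matched lists (percentile 0.425). The percentile was 0.555 with windows of 3 kb or of 500 bp and 0.695 with q under 0.05. It was 14.1 with the strongest 20000 peaks of each list and 26.6 for the 11 genes with windows free of other genes. At a −log10 q of at least 5 in both lists 7 of 13 lacked one (16.1), and 2 of 2 did at 10 (57.5). Over whole genes with 5 kb on both sides 1 of 40 did (5.4). In the opposite direction 0 of 36 genes lacked a wild-type peak, against a mean of 5.19 (percentile 0.140). All 22 DNA repair genes were marked in the KAT8-deficient list and 17 in wild type, with Ercc1 (3.18), Lig4, Trp53bp1, Xrcc5 (3.42) and Xrcc6 in the KAT8-deficient list only. Those 5 of 22 compare with a mean of 3.58 in matched lists (percentile 79.9), and the 0 of 17 wild-type genes without a KAT8-deficient peak with a mean of 2.43 (percentile 2.88). With q under 0.05, 4 of 17 lacked one (percentile 37.5), and the percentile was 1.66 with windows of 500 bp, 2.25 matched on −log10 q and 0.475 without matching. Of 76 cytosolic ribosomal protein genes, 41 were marked in both lists, 15 in wild type only, led by Rps27 (4.07) and Rpl13 (4.01), and 8 in the KAT8-deficient list only, led by Rpl23a (3.27) and Rpl39 (2.99), at percentile 64.0.

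Of 30 lysosome and autophagy genes, 18 were marked in both lists, 10 in wild type only, led by Mcoln1 (3.32) and Gabarapl1 (3.18), and Ctsd (2.59) in the KAT8-deficient list only (percentile 77.4). Of 28 acetyltransferases, deacetylases and acetyl readers, 18 were marked in both lists, 4 in wild type only, led by Hdac8 (3.66) and Sirt6 (3.21), and 2 in the KAT8-deficient list only, Naa60 (3.20) and Hdac10 (2.18), at percentile 32.7. The peaks at Ctsd (−log10 q 1.21) and Hdac10 (0.384) did not reach a q-value under 0.05.

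Of genes of other cell types, both lists marked 2 of 12 T cell genes, 2 of 12 B cell genes, 2 of 14 neutrophil genes, 3 of 11 erythroid and megakaryocyte genes, 2 of 10 dendritic cell genes and 1 of 12 fibroblast genes, with percentiles of 65.7, 39.8, 58.7, 27.4, 75.2 and 73.5. The share of macrophage identity genes marked in both lists, 7 of 28, lay among these. Counted in each list by itself, 15 of the 28 were marked in wild type and 9 in the KAT8-deficient list. The other cell types, in the same order, had 4, 3, 3, 3, 3 and 3 genes marked in wild type. In the KAT8-deficient list they had 3, 2, 2, 3, 3 and 1. Among these cell types the macrophage share was thus the highest in wild type, and only just so in the KAT8-deficient list. Of all protein-coding genes, 46.8% were marked in wild type and 43.3% in the KAT8-deficient list. The 15 of 28 macrophage genes were therefore near the share of all genes, and the 9 of 28 under it. Genes of the other cell types in wild type only were Lck, Zap70, Blk, Prtn3, Batf3, Thy1 and Postn, and in the KAT8-deficient list only Cd8b1 and Zbtb46. Of these single-list peaks, only that at Blk had a q-value under 0.05 (−log10 q 1.36). Gp9 was the strongest shared erythroid and megakaryocyte gene (4.31 in wild type). Of 22 genes of unrelated tissues, 0 were marked in both lists and 3 in wild type only, Dlx5, Neurog2 (3.18) and Nkx2-5 (2.59, with a −log10 q of 0.743), at percentile 96.0. Over the 21 lists, 1 lay in the upper 2.5% of random lists and 1 in the lower 2.5%. Chance alone gives about 1.05 lists in both tails together if every list can reach them. Small lists may not: unrelated tissues with 3 of 3 genes lost stood at 96.0, and the erythroid and megakaryocyte list with 0 of 3 at 27.4. In the opposite direction, ranked after the data were examined, 2 of 20 lists, the TLR7 pathway and the respiratory chain, lay in the lower 2.5% and 0 in the upper.

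**Figure D3:**
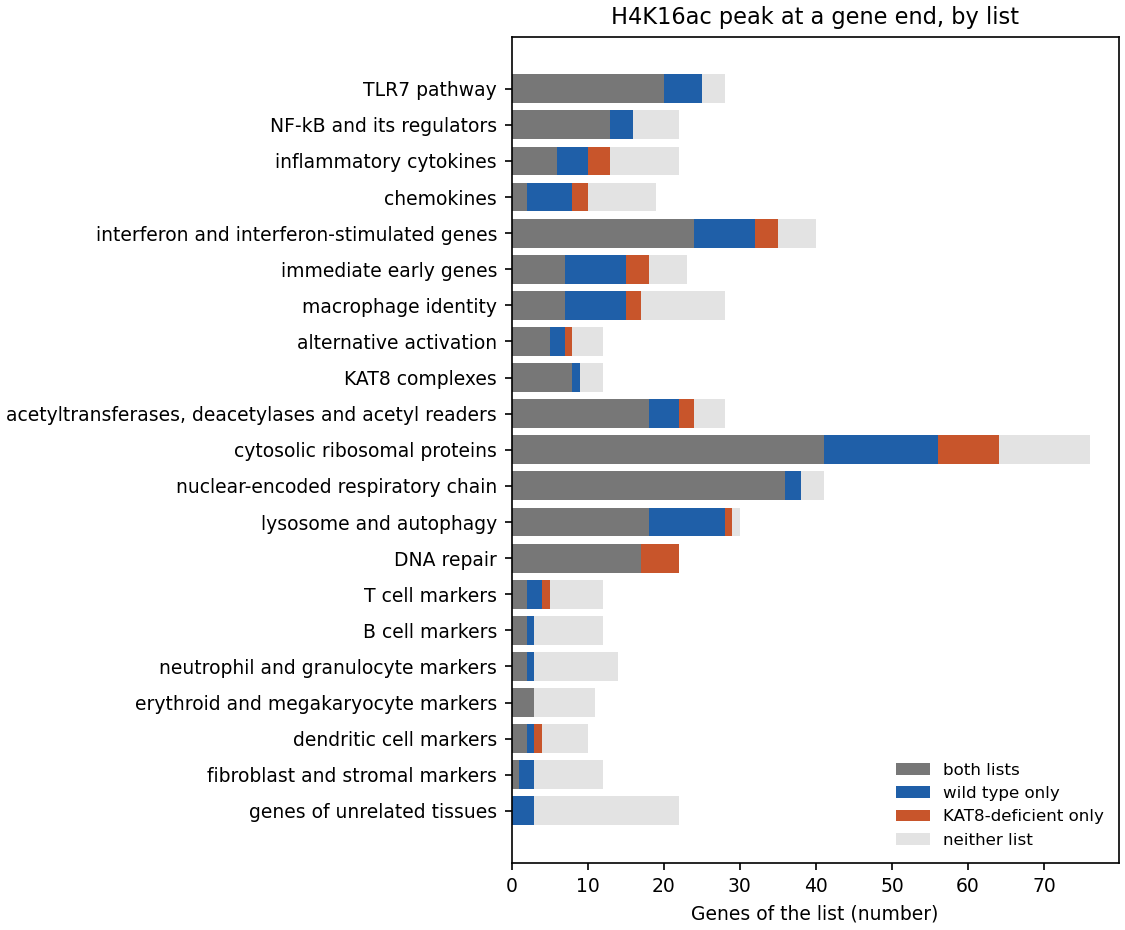
Number of genes of each fixed list with an H4K16ac peak within 1 kb of a gene end in both lists (dark grey), in wild type only (blue), in the KAT8-deficient list only (orange) or in neither (light grey). Respiratory chain genes were mostly in both lists (36 of 41), and chemokine genes in wild type only (6) or neither (9).

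X-linked genes with a wild-type peak lacked a KAT8-deficient one more often than autosomal genes. On the X chromosome 179 genes had a wild-type and 115 a KAT8-deficient peak, 18.5% and 11.9% of its genes, against 48.7% and 45.2% of autosomal genes. Of the 179 genes, 98 lacked a KAT8-deficient peak, 54.7% (47.4 to 61.9), against 23.0% (22.2 to 23.9) of autosomal genes and 15.6% to 29.2% on single autosomes. Matched random lists lost 43.1 genes on average and 62 at most. Among 27 X-linked genes with a wild-type −log10 q of at least 5, 8 lacked any KAT8-deficient peak: Fancb, Mospd2, Upf3b, Ap1s2, Tab3, Siah1b, Suv39h1 and Slc25a53, of which those other than Fancb, Mospd2 and Tab3 are named here after their values were seen. Kdm6a and Ikbkg, likewise, were marked in both lists. In the other direction, 34 of 115 X-linked genes with a KAT8-deficient peak lacked a wild-type one (mean 24.3 in matched lists, percentile 98.9).

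The same excess was not seen over all X regions. Of these, 37.5% (34.2 to 41.0) of 773 in wild type and 47.1% (43.2 to 51.0) of 616 in the KAT8-deficient list were shared, against 33.2% and 35.5% on autosomes. At gene ends the X had 177 wild-type and 107 KAT8-deficient regions, a ratio 0.653 times the autosomal one (0.513 to 0.831); away from gene ends it had 596 and 509, 0.894 times the autosomal ratio (0.794 to 1.01). The comparison by genes was made after the data were examined, and 6 of 21 chromosomes, 5 of them autosomes, lay in the outer 5% of random lists, where independent genes give about 1.05. The difference between the ratios at and away from gene ends was not tested. Of 4 single-copy Y genes, Eif2s3y had a wild-type peak (fold 3.91) and Ddx3y, Kdm5d and Uty had none in either list. The whole Y chromosome held 174 wild-type and 136 KAT8-deficient regions, a ratio 0.823 times the autosomal one (0.657 to 1.03).

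**Figure D4:**
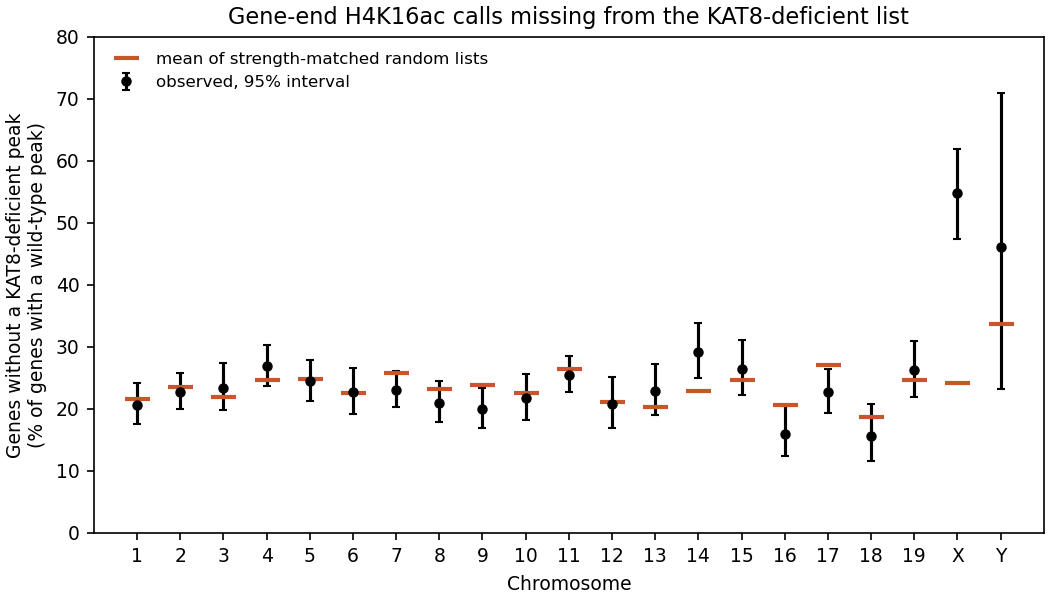
Genes without a KAT8-deficient peak as a share (%) of genes with a wild-type peak, by chromosome; points are observed shares, bars 95% Wilson intervals and orange dashes the mean of strength-matched random lists. The X chromosome stands at 54.7%, and the autosomes lie between 15.6% and 29.2%.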

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

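With 1 library per group, no replicate could be left out and no difference has a replicate check. No paired analysis was possible because each group has 1 library. The q under 0.05 setting, windows free of other genes, matching on −log10 q or on shared windows, the opposite direction, the X gene shares and a gene's peak lacking any overlap in the other list were chosen after the data were examined. Base composition was not run, and taking peaks as listed rather than merged moved nothing because no peaks touched. Of 133 alternative values, 57 stayed within their interval or within 1.5 times the count, 75 moved and 1 reversed; the cause was not tested except where a smaller set of peaks or genes sets the value. Read totals were not used here, so the lists limit every absence to a call under the peak caller's threshold.

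The number of regions fell to 4147 and 2679 (wild type, KAT8-deficient) at a −log10 q of at least 5, to 1187 and 743 at 10, and to 20000 each for equal lists. The share of regions overlapped was 44.2% and 68.7% with at least 5 in both lists, 45.6% and 73.1% with at least 10, 42.2% and 42.7% for the strongest 20000, and 38.0% and 40.6% with q under 0.05. It was 24.7% and 28.1% with 50% of the region covered, 35.0% and 37.2% with summits within 500 bp, and 33.9% in wild type after merging peaks within 1 kb. Against all peaks of the other list it was 94.6% and 96.2% for regions of at least 5, and 99.2% and 99.6% for those of at least 10. In the strongest 10% it was 79.3% and 81.0% with 50% covered, 87.4% and 85.3% by summits, and 90.9% and 88.7% after merging. The X minus autosome difference in this share, 4.34 points in wild type and 11.6 in the KAT8-deficient list, was in wild type 1.03 at 5, 0.997 for equal lists and 9.11 at 10. In the KAT8-deficient list it was 2.44 at 5, 7.02 for equal lists, and reversed to -11.5 at 10.

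Genes called in wild type only numbered 1719 at 5, 546 at 10, 1464 with windows free of other genes and 87 for wild-type peaks of at least 5 against all KAT8-deficient peaks in the window. Genes in the KAT8-deficient list only numbered 307 at 5, 65 at 10, 1076 with free windows and 12 against all wild-type peaks. Genes in both numbered 1004 at 5, 117 at 10, 4878 for equal lists, 4084 with free windows and 2931 against all peaks. The share of regions at gene ends was 54.6% and 40.8% at 5, 45.3% and 20.9% at 10, 33.0% and 28.5% for equal lists, 18.3% and 17.7% after merging, 27.7% and 27.2% with windows of 3 kb, and 15.3% and 14.7% with 500 bp. The ratio of KAT8-deficient to wild-type counts, chosen after the data were examined, was 0.921, 0.861, 0.483 and 0.288 at gene ends and 0.953, 1.07, 0.842 and 0.906 away from them, for all regions, equal lists, 5 and 10. Fixed gene lists in the upper 2.5% of random lists numbered 1 as reported. They were 0 at 5, at 10, for equal lists, with free windows and against all peaks; 2 with windows of 3 kb, over whole genes with 5 kb on both sides and matched on −log10 q; and 4 without matching. Lists in the lower 2.5% numbered 1. They were 0 at 5, at 10, for equal lists, with free windows, against all peaks and over whole genes; and 2 with windows of 500 bp, with q under 0.05, without matching and matched on −log10 q. The lists that entered the upper 2.5% were the genes of unrelated tissues (3 kb, whole genes, unmatched), immediate early genes (unmatched, matched on −log10 q) and macrophage identity (unmatched). Those that entered the lower 2.5% were DNA repair (500 bp, unmatched, matched on −log10 q) and interferon genes (q under 0.05). At the strict thresholds few genes per list remain, so a count of 0 there carries little weight.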

Other observations

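The tests of background pileup, the ratio for equal numbers of peaks, the tests of windows free of or shared with neighbours and of matching on −log10 q, the share of X-linked genes, the ratio of Y regions, the gene families and the values by chromosome were chosen after the results were seen. Among families taken by symbol, olfactory receptor genes were rarely marked, with 29 of 1110 in wild type and 25 in the KAT8-deficient list. Of those 29, 21 lacked a KAT8-deficient peak, against a mean of 11.5 in strength-matched lists (percentile 99.98). Of 397 Zfp zinc finger genes, 62.0% were marked in wild type and 59.7% in the KAT8-deficient list, with 42 of 246 lacking a KAT8-deficient peak (percentile 8.91, or 0.155 for windows free of other genes). Proteasome subunit genes were marked in 35 of 40 cases in wild type and 26 in the KAT8-deficient list (percentile 97.1), and vacuolar ATPase genes in 16 and 9 of 26 (98.5, or 73.3 with free windows). Keratin genes were marked in 6 and 12 of 53, and vomeronasal receptor genes in 6 and 16 of 353. These are 6 of 13 families looked at.

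The KAT8-deficient list held fewer regions above a −log10 q of 5, with a ratio of 0.483 at gene ends that was 0.861 for equal numbers of peaks. A shallower KAT8-deficient library is argued against by the background pileup inferred from the steps between fold values, which was 3.68 there and 3.09 in wild type, a ratio of 1.19. This takes the fold as pileup plus 1 over background plus 1, rests on the 43.2% and 36.5% of peaks on the genome-wide background, and assumes equal read extension, for which the smallest peak width of 200 bp in both lists is the only evidence. A lower ratio of signal to background at every gene end alike stays open: 0 of the 6 gene lists with at least 5 strong genes stood apart, too few to decide. With 1 library per genotype, the efficiency of the reaction and the loss of KAT8 cannot be told apart, and either may lie behind the difference.

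X-linked gene ends with a wild-type peak lacked a KAT8-deficient one in 54.7% of cases. Weaker called peaks on the X are argued against, since the share stood at percentile 100 of lists matched on the fold of called peaks. This also held when matched on −log10 q and with windows free of other genes (58 of 105, where no random list lost more than 45). Matching on called peaks cannot tell whether more of the X calls were false, so that stays open. Nor were the lists matched on how densely regions lie. The KAT8-deficient list held 63.8 regions per 100 genes on the X and 263 on autosomes, so the sparse marking of the X stays open too. Olfactory receptor genes, which were also rarely marked, lost 21 of 29 calls (percentile 99.98). At a wild-type −log10 q of at least 5, 8 of 27 X-linked genes lacked any KAT8-deficient peak, against a mean of 0.897 in matched lists. A lower X copy number was to be set aside if the upper bound of the X to autosome ratio away from gene ends reached 0.95; the ratio was 0.894 (0.794 to 1.01), but a wide interval meets that bound by its width alone, so it was read as open once the value was seen. A female wild-type and a male KAT8-deficient animal would give more Y regions in the KAT8-deficient list. There were fewer, 136 against 174, and the ratio to autosomes was 0.823 (0.657 to 1.03), so the Y regions went against it. The Y gene test asked for 2 of 4 genes with a wild-type peak and found 1, Eif2s3y, so that test did not decide. With 1 library per group, the sex of the animals was not settled. An effect of KAT8 loss on the X was not tested apart from these, and the excess ran in both directions, since 34 of 115 X-linked genes with a KAT8-deficient peak lacked a wild-type one (percentile 98.9).

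With all peaks counted, respiratory chain genes lacked a KAT8-deficient peak less often than matched genes (percentile 0.425). The percentile was 16.1 at a −log10 q of at least 5 in both lists. Matching on −log10 q in place of fold (percentile 0.910) and matching also on whether windows overlap a neighbour's (0.730) argue against stronger peaks or shared windows as the whole cause, although genes with shared windows lost the call less often, 20.4% against 26.4%. The percentile of 26.6 among genes with free windows was first read in favour of neighbouring peaks; it was later set aside, because with 11 such genes the lowest percentile in reach is 6.16. This list was 1 of 21, of which about 1.05 fall outside by chance if every list can reach the tails. In the opposite direction 0 of 36 genes lacked a wild-type peak (percentile 0.140), over largely the same genes, and chance was not tested further.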
